A study of Mus musculus with 6 samples.

How the data were processed

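Poly(A)-selected RNA from 6 samples of RAW264.7, a mouse macrophage line that arose in an ascites tumour induced by Abelson leukaemia virus, was sequenced with a directional library kit from 1 µg of RNA, per the labels' protocols. Sample titles place 3 libraries in a control siRNA group and 3 in a Nop16 siRNA group, and the treatment tag is "no" for all 6. The single treatment text given for all samples describes a Nop16 siRNA at 20 nM for 3 days. Whether the controls received a non-targeting siRNA in the same way, and the sequence of any siRNA, are not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

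The deposited values are raw counts of fragments per gene. They were made with featureCounts 2.0.1 in paired mode on Ensembl release 101 gene models of the GRCm38 build, per the file headers. The headers also record strand setting 2, a minimum overlap of 10 bases, only properly paired fragments, and counting of multi-mapped fragments and of fragments that overlap several genes. A fragment can thus be counted for more than 1 gene. Totals are therefore not numbers of distinct fragments, and the counts of paralogs, pseudogenes and overlapping genes are uncertain. The gene models carry a filter that the headers name but do not describe. Trim Galore, whose version is not given in the sources used here, and HISAT2 2.2.1 are named in the submitters' processing notes, with GRCm38 (mm10) as the build. Each count table lists 55401 genes, all of them used as deposited. Symbols were matched for 55141 identifiers. Gene biotypes, transcript sequences and 3' UTRs came from GENCODE release 21 for mouse, which is on the same build but older than the models counted. Coordinates are those of the count tables.

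Total counts ran from 15601477 to 23061922 per library. A gene with 3 counts lies at 0.13 to 0.192 CPM (counts scaled by library size), which is taken as the floor. Such floors cover counting error only, since the libraries carry no molecular identifiers. Within a group, chi-square per degree of freedom between libraries was 2.52 to 3.12, so no pair agreed within sampling noise, and between groups it was 45.5 to 52.5.

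Counts were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with robust dispersion, TMM scaling and the filterByExpr filter, and a Benjamini-Hochberg adjusted p below 0.05 was the threshold. Log2 fold changes are Nop16 siRNA minus control siRNA, and their SE is the log2 fold change divided by the root of the test's F. CPM are given as mean ± SD over 3 libraries. Of 29 gene lists with 1112 entries, 1111 entries were matched to a gene, and the 23 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log CPM with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The estimate rests on only 3 libraries per group, so a list that misses the threshold with it may still have moved. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

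The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Nop16, then the 10 largest rises and the 10 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM and fully separated groups. It then takes up to 4 changed members of each list with the largest change, every tested member of the PRC2 and H3K27 demethylase list, and up to 2 of the most abundant members where a list had fewer than 2 changed members. Some list members that the rule takes are left unnamed in the text. The alternatives were other scalings, DESeq2 1.42.0, limma-voom, no filter and a filter of 5 CPM in 3 libraries, robust dispersion off, a block for the replicate number, minimum folds of 1.2 and 1.5, and leaving out each library. Removal of length and GC trends, thinning to equal depth, protein-coding genes only, and scaling without ribosomal protein genes and pseudogenes were added after the data were seen.

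The tests were tried on simulated counts for 14301 genes drawn from the control means and the library sizes of this comparison. At each of 4 sizes, 50 genes with a mean of at least 5 CPM were changed. That is a far smaller share than was called in the data. The edgeR test recovered 48% of genes changed 1.2-fold, 98% at 1.5-fold and 100% at 2-fold and 3-fold, and 8 of its 181 calls (4.42%) were false. The list test, the trend removal, the matched random lists and the search of 3' UTRs were each tested on simulated data too. Overlapping genes were found with bedtools 2.31.1. Pseudogenes were matched to ribosomal protein genes with BLAST 2.17.0 at 85% identity or more over at least 50% of the pseudogene. The search of 3' UTRs took protein-coding genes with a mean of at least 5 CPM and an annotated 3' UTR of at least 50 bases, and heptamers with at least 50 carriers. Fold changes there were first adjusted for 3' UTR length, GC content and expression. Each heptamer's z was set against 100 permutations of the fold changes. The 14 further lists of the closing section were written after the main list results were seen. Medians of lists there carry intervals from 2000 bootstrap draws over genes. No sample was left out.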

Results

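RNA-seq counts were obtained from RAW264.7 cells, a mouse macrophage line, in 3 control siRNA libraries and 3 Nop16 siRNA libraries. The series asks what NOP16, a nucleolar protein of large ribosomal subunit assembly, does in macrophages, and its title links the protein to methylation of histone H3 at lysine 27 and to gene repression. Total counts were 21799500, 23061922 and 19778237 in control replicates 1, 2 and 3, and 15601477, 17484126 and 18635089 in Nop16 siRNA replicates 1, 2 and 3, so each control library was deeper than each Nop16 siRNA library. The labels do not say whether the control cells were transfected in the same way, so a response to transfection itself is not separated here from one to Nop16 siRNA.

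Nop16 RNA fell to 22.4% of its control level (95% interval 19 to 26.4%). The gene (ENSMUSG00000025869) lies on chromosome 13 from 54584185 to 54590090 on the minus strand of GRCm38. It had 388, 437 and 402 counts in control replicates 1 to 3, and 61, 72 and 84 counts in the Nop16 siRNA replicates. In CPM this was 19.02 ± 1.27 against 4.18 ± 0.303 (SD, n = 3 each). The log2 fold change was -2.16 (SE 0.12, edgeR adjusted p = 2.94e-23).

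**Figure D1:**
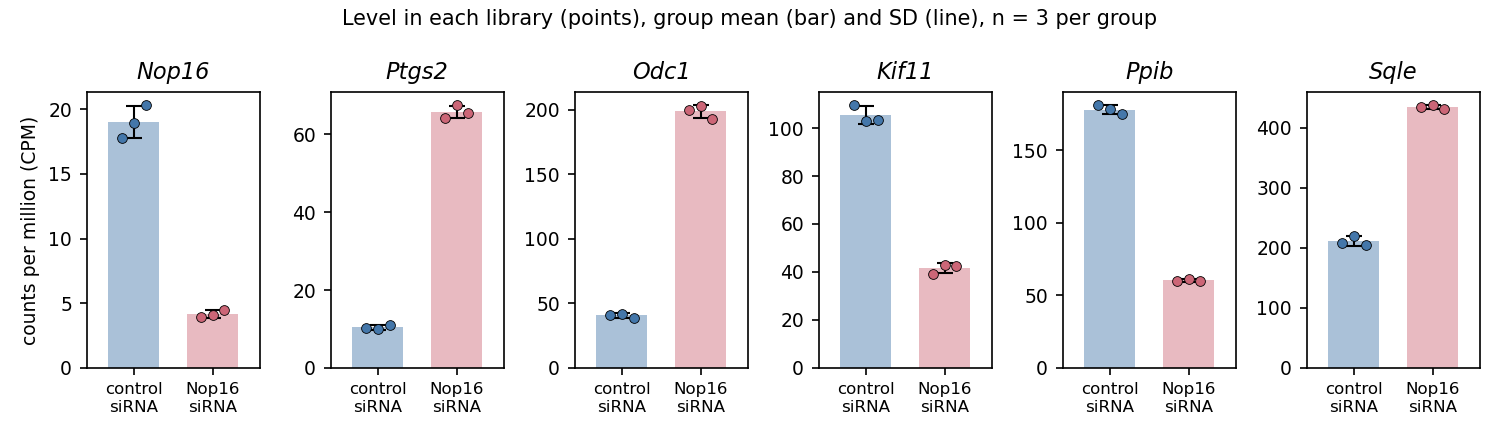
CPM (counts scaled by library size) in each library for Nop16 and 5 other genes, with control siRNA in blue and Nop16 siRNA in red; points are libraries, bars are group means and lines are SD (n = 3 per group). Nop16 fell from a mean of 19.02 to 4.18 CPM, Kif11 from 105 to 41.6 and Ppib from 178 to 60.3, while Ptgs2 rose from 10.4 to 65.8 CPM.

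Inflammatory and macrophage genes led the rises after Nop16 siRNA among protein-coding genes with a mean of at least 5 CPM and fully separated groups. Some genes below 5 CPM moved more. Acod1, which makes itaconate in activated macrophages, rose 7.41-fold (log2 fold change 2.89), and Ptgs2, the inducible cyclooxygenase, rose 6.44-fold (2.69). Clec4n, which encodes the fungal pattern receptor dectin-2, rose 5.64-fold, the monocyte chemokine gene Ccl7 5.45-fold, and Odc1, the rate-limiting enzyme of polyamine synthesis, 4.97-fold. Ms4a7 (4.92-fold), Krt23 (4.69-fold), Pcdh7 (4.27-fold), the interleukin-1 receptor antagonist gene Il1rn (4.06-fold) and the integrin gene Itgax (3.88-fold) completed the 10 largest rises at that level. The edgeR adjusted p of these 10 genes was 1.06e-19 or lower.

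At the same level, the falls were led by Lcn2, an iron-sequestering secreted protein, at a log2 fold change of -2.37, followed by Nop16 and by Dbp, a clock-controlled transcription factor, at -2.15. Sh2d6 (-1.69), the cyclophilin B gene Ppib (-1.54), Rps29 (-1.52), the basement membrane gene Nid2 (-1.49), Rps20 (-1.37), Rpl22l1 (-1.32) and the mitotic kinesin gene Kif11 (-1.31) were the other large falls. Rps29 had an edgeR adjusted p of 0.000266, and the rest had 4.95e-12 or lower. The annotated 3' UTRs of Ppib, Rps29 and Kif11 hold the 8-base sequence ACTACCAA, which also occurs in the Nop16 transcript. That sequence was picked on these same fold changes, so its presence here is no separate evidence. It occurs in 1.55% of the genes in the search of 3' UTRs.

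Of 14269 genes tested, 6482 (45.4%) changed at an edgeR adjusted p below 0.05, with 3287 higher and 3195 lower. Most changes were small, with a median absolute log2 fold change of 0.341 among changed genes. More than 2-fold differences were found for 215 higher and 210 lower genes. The 3 libraries of one group lay above all of the other for 7499 genes (52.6%, against 10% by chance). Tested against a minimum fold of 1.2, 2361 genes passed, and 545 passed against a minimum of 1.5.

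**Figure D2:**
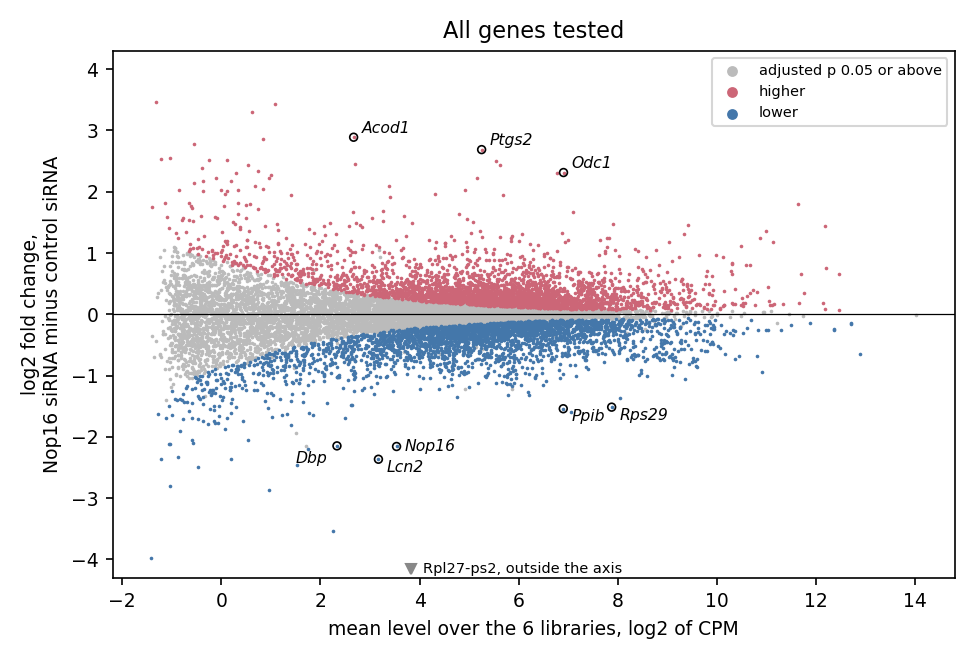
Log2 fold change (Nop16 siRNA minus control siRNA) against the mean level over the 6 libraries on a log2 CPM axis, one point per gene tested; red and blue mark the 3287 higher and 3195 lower genes. Ringed genes are Nop16 and 7 of the genes named in the text, and the triangle marks Rpl27-ps2, a pseudogene below the axis range that did not pass the test.

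Genes of the cell division programme fell together. All 64 tested G2/M and mitosis genes were lower, with a median log2 fold change of -0.87, and the same 64 passed when adjusted over the list alone. Kif11 fell from 105 ± 3.69 to 41.6 ± 2.05 CPM, Ccnb2, a mitotic cyclin, from 104 ± 3.56 to 42.5 ± 2.82, the spindle gene Knstrn from 81.6 ± 0.49 to 35.7 ± 2.17, and the checkpoint kinase gene Bub1b from 92.1 ± 2.74 to 40.8 ± 0.564 (SD, n = 3 each). Of 67 genes of S phase and E2F control, 64 were lower and none were higher, or 66 when adjusted over the list alone, with a median of -0.42. E2f2 fell by 1.12 on the log2 scale, the replication helicase gene Mcm5 by 0.74, Mybl2 by 0.73 and the thymidylate synthase gene Tyms by 0.73. Both lists passed camera (adjusted p = 1.63e-31 and 1.09e-20) and also passed with an estimated correlation (adjusted p = 0.0132 and 0.013). Of 21 replication-dependent histone genes tested, 10 were lower and 2 higher (11 and 2 adjusted over the list alone), with a median of -0.69 and a camera adjusted p of 0.0331. This call was lost at adjusted p = 0.393 with an estimated correlation. It was also lost without control replicate 1 (0.0852), without control replicate 3 (0.0625) and without Nop16 siRNA replicate 3 (0.0529), as well as with scaling by library size only (0.0546), in limma-voom (0.052), with the stricter filter (0.12), with length and GC trends removed (0.0772) and with thinning to equal depth (0.0517). Leaving out control replicate 1 or 3, or Nop16 siRNA replicate 1 or 3, left 1 histone gene higher. These transcripts mostly lack a poly(A) tail, and the largest fall, of Hist1h2ad, was from 0.899 ± 0.185 to 0.232 ± 0.203 CPM.

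Genes for the proteins of the cytosolic ribosome were lower almost without exception. Of 81 tested, 80 were lower and none were higher, both over all genes and adjusted over the list alone, with a median log2 fold change of -0.62. Rps29 fell from 349 ± 25.4 to 120 ± 12.2 CPM, Rps20 from 381 ± 5.4 to 146 ± 6.39, Rpl22l1 from 79.4 ± 2.44 to 31.4 ± 2.61 and Rpl12 from 728 ± 10.7 to 360.3 ± 8.48 (SD, n = 3 each). Together these genes held 4.73% ± 0.077 of the counts in control libraries and 3.02% ± 0.081 after Nop16 siRNA. The list passed camera at an adjusted p of 3.39e-32 but not with an estimated correlation, where its genes varied together (adjusted p = 0.185 with an estimated correlation). Multi-mapped fragments were counted, and pseudogenes matched to these genes moved with them, with 180 of 278 lower and none higher.

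Ribosome assembly genes did not share that direction. Among 58 large subunit assembly factors other than Nop16, 16 were higher and 8 lower (15 and 8 adjusted over the list alone), with a median of 0.07 and a camera adjusted p of 0.201. Surf6 rose 2.03-fold, while Nop53, Nsa2 and Npm1 (nucleophosmin) fell by 0.67, 0.63 and 0.48 on the log2 scale. Among 59 genes of the small subunit processome, snoRNPs and RNA polymerase I, 17 were higher and 6 lower (17 and 5 adjusted over the list alone; camera adjusted p = 0.3). Rrp12 rose 1.53-fold, and Polr1c fell by 0.40.

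Several core subunits of PRC2, the complex that methylates H3 lysine 27, fell modestly. The catalytic subunit gene Ezh2 fell from 69.5 ± 1.3 to 44.1 ± 1.1 CPM (log2 fold change -0.64, SE 0.0528, edgeR adjusted p = 6.07e-16), and Suz12 from 121 ± 4.32 to 88.3 ± 2.59 CPM (-0.43, SE 0.0419). Phf19 (-0.61), Rbbp4 (-0.36), Ezh1 (-0.32), Eed (-0.17) and Aebp2 (-0.17) were also lower, and Epop (0.49), Phf1 (0.27) and Jarid2 (0.25) were higher. Mtf2 (0.18, edgeR adjusted p = 0.134), Rbbp7 (-0.04, 0.41) and the demethylase genes Kdm6a (-0.03, 0.862) and Kdm6b (-0.26, 0.385) did not pass. Of the 14 genes, 3 were higher and 7 lower, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.157). Several calls near the threshold depended on the setting. Eed's was lost without control replicate 3 (edgeR adjusted p = 0.0686), without Nop16 siRNA replicate 3 (0.15), in DESeq2 (0.0518) and with thinning to equal depth (0.0561), Aebp2's without Nop16 siRNA replicate 1 (0.0632) and Jarid2's without control replicate 1 (0.052). Mtf2 passed without Nop16 siRNA replicate 1 (0.0255) and with length and GC trends removed (0.0454), and Kdm6b without Nop16 siRNA replicate 2 (log2 fold change -0.66, 0.0336).

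Of 20 genes of PRC1, the complex that ubiquitinates histone H2A, 11 were lower and 2 higher (12 and 2 adjusted over the list alone), with a median of -0.17. Leaving out any 1 library other than control replicate 2 left 1 higher. Yaf2 (-0.66), Pcgf5 (-0.66), Cbx7 (-0.58) and Bcor (-0.50) fell most. The list passed camera (adjusted p = 0.012) but not at adjusted p = 0.116 with an estimated correlation. Developmental transcription and signalling genes that Polycomb represses in many cell types were mostly below the level needed for testing, which 30 of 127 reached. Of these, 6 were lower and 2 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.437), and without Nop16 siRNA replicate 2 these were 3 and 1. Without control replicate 2 or 3, 1 was higher. Pax6 (-0.66) and Hoxb6 (-0.73) fell. Hoxa9 (-0.97) and Hoxa5 (-0.83) passed at adjusted p = 0.0196 and 0.0481 in edgeR but not in DESeq2 (0.0933 and 0.156), at under 2 CPM. Hoxa9 lost its call without control replicate 2 (0.168), Nop16 siRNA replicate 2 (0.102) or Nop16 siRNA replicate 3 (0.138), and with thinning to equal depth (0.0743). Its log2 fold change was -1.49 without Nop16 siRNA replicate 1. Hoxa5 lost its call without control replicate 1 (0.199), control replicate 3 (0.0798), Nop16 siRNA replicate 2 (0.0642) or Nop16 siRNA replicate 3 (log2 fold change -0.50, 0.318). It also lost it with a block for the replicate number (0.0553), no filter (0.0689), robust dispersion off (0.0558) and thinning to equal depth (0.0529).

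Inflammatory genes of the NF-kB programme rose on the whole. Of 49 tested, 35 were higher and 5 lower (35 and 6 adjusted over the list alone), with a median log2 fold change of 0.53. Besides Acod1, Ptgs2 and Ccl7, the cytokine gene Il1b rose 7.26-fold from 0.434 ± 0.225 to 3.13 ± 0.549 CPM. Lcn2, a secreted product of the same programme, went the other way. Of 47 macrophage identity genes, 33 were higher and 4 lower, the same numbers as adjusted over the list alone, with a median of 0.34. Lyz2, lysozyme, rose 2.57-fold from 1151 ± 153 to 2908 ± 176 CPM, the chemokine receptor gene Ccr2 2.43-fold and Clec4d 2.38-fold. Both lists passed camera (adjusted p = 2.64e-10 and 1.22e-08). Neither passed with an estimated correlation: the NF-kB list had adjusted p = 0.0945 with an estimated correlation, and the macrophage list had adjusted p = 0.07 with an estimated correlation. Of 56 interferon-stimulated genes, 22 were higher and 5 lower (22 and 5 adjusted over the list alone), with a median of 0.14 and a camera adjusted p of 0.0164. That call was lost at adjusted p = 0.266 with an estimated correlation. Lgals3bp rose 1.59-fold and Ifi27 1.47-fold, and Ifi35 fell by 0.63 on the log2 scale. Zbp1 (1.59), at under 1 CPM, passed in edgeR (adjusted p = 0.0105) but not in DESeq2 (0.0624), without control replicate 1 (0.0859) or without Nop16 siRNA replicate 1 (0.0502).

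Sterol synthesis and lysosomal genes were also higher. Of 25 cholesterol synthesis genes, 23 were higher and none lower, also when adjusted over the list alone, with a median of 0.66. Squalene epoxidase (Sqle) rose 2.09-fold from 211 ± 8.25 to 435 ± 3.03 CPM, Hsd17b7 2.26-fold, Idi1 2.07-fold and Cyp51 1.98-fold. Of 47 lysosomal genes, 32 were higher and 6 lower, also when adjusted over the list alone, with a median of 0.23. Gpnmb rose 1.77-fold, the protease genes Ctsb 1.69-fold and Ctsd 1.58-fold, and the autophagy gene Gabarapl1 1.66-fold. Ctsd shares 34.4% of its exonic length with another gene model, so its count is uncertain. Both lists passed camera (adjusted p = 4.96e-11 and 5.4e-06) and passed with an estimated correlation (adjusted p = 0.0132 and 0.0347).

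**Figure D3:**
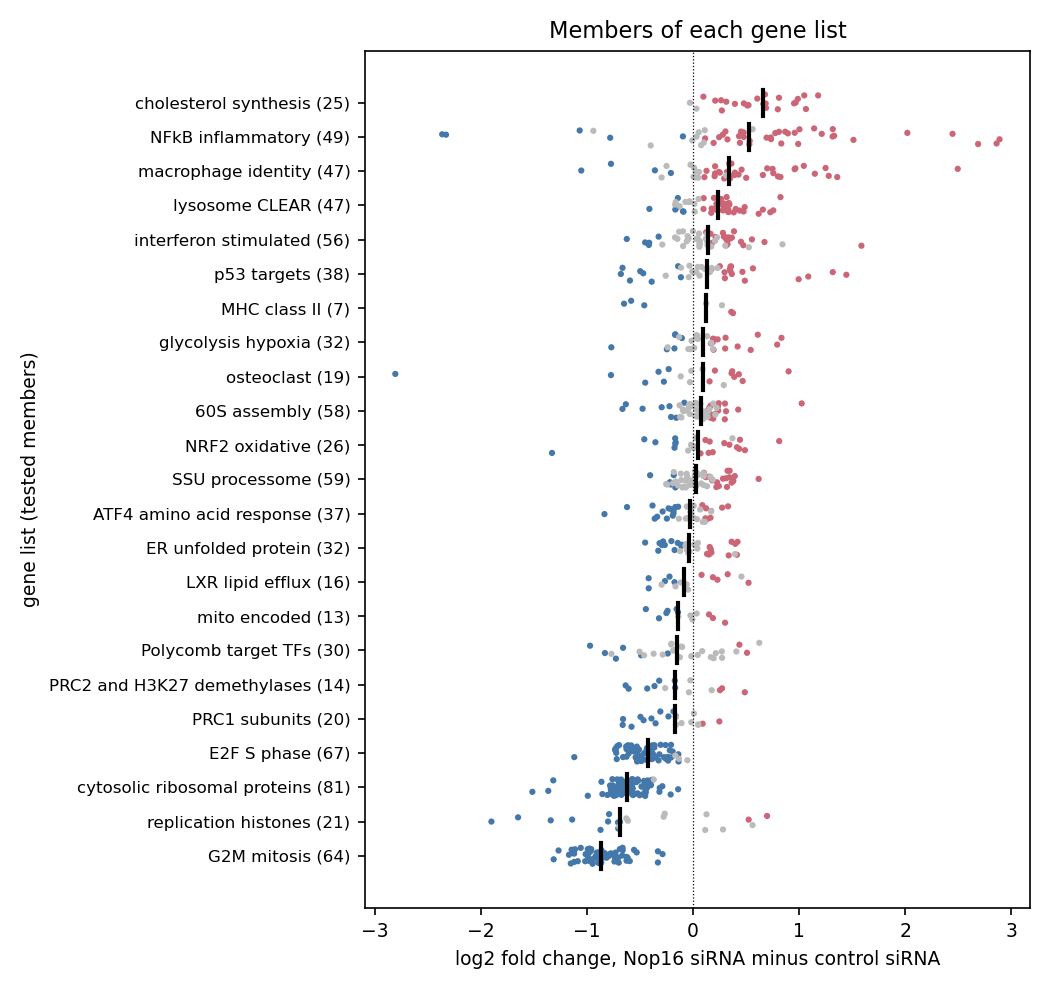
Log2 fold change (Nop16 siRNA minus control siRNA) of each tested member of the 23 gene lists, one point per gene, in red if higher, blue if lower and grey if not past the threshold; black lines are list medians and list sizes are in brackets. The G2/M list (median -0.87) and the ribosomal protein list (-0.62) lie to the left, and the cholesterol synthesis list (0.66) lies farthest to the right.

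The other lists did not pass camera. Of 38 p53 target genes, 16 were higher and 8 lower (16 and 8 adjusted over the list alone), with an adjusted p of 0.067. Cd80 rose 2.72-fold, Fas 2.49-fold, Plk3 2.12-fold and Phlda3 1.99-fold. The p53 list passed without control replicate 2 (0.0483), without Nop16 siRNA replicate 1 (0.0369) and with no filter (0.0352). Amino acid response genes under ATF4 had 8 higher and 14 lower of 37 (9 and 14 adjusted over the list alone; camera adjusted p = 0.3), and Trib3 fell by 0.84 and Ddit3 by 0.62 on the log2 scale. Hypoxia and glycolysis genes had 13 higher and 6 lower of 32 (14 and 6 adjusted over the list alone, camera adjusted p = 0.117). The glucose transporter gene Slc2a3 rose 1.78-fold, and Pdk1 fell by 0.77 on the log2 scale. Oxidative stress genes under NRF2 had 12 higher and 7 lower of 26, also adjusted over the list alone (0.178), and ferritin heavy chain (Fth1) rose 1.76-fold. The NRF2 list passed in limma-voom (0.0454). Nqo1 (-1.33) passed in edgeR (adjusted p = 0.0116) but not in DESeq2 (0.0721), nor without control replicate 1 (0.108), Nop16 siRNA replicate 1 (0.0674) or Nop16 siRNA replicate 3 (0.0635). Unfolded protein response genes had 11 higher and 11 lower of 32 (11 and 12 adjusted over the list alone; 0.761), and their median and mean differed in sign. Lipid efflux genes under LXR had 5 higher and 5 lower of 16, also adjusted over the list alone (camera adjusted p = 0.754). Abca1 rose 1.44-fold, and Srebf1 and Mylip each fell by 0.42 on the log2 scale. Of 19 osteoclast genes, 8 were higher and 6 lower (9 and 6 adjusted over the list alone, camera adjusted p = 0.437). Their median and mean differed in sign. Ocstamp fell by 2.81 on the log2 scale, at under 1 CPM, and Src rose 1.87-fold. Of 7 MHC class II genes, 2 were higher and 3 lower, also adjusted over the list alone (0.826), and their median and mean differed in sign. Without any 1 library, 1 MHC class II gene was higher, and the sign of the median also turned with no filter and with the stricter filter. Of 13 mitochondrially encoded genes, 3 were higher and 6 lower, also adjusted over the list alone (0.317), but with length and GC trends removed 6 were higher and 4 lower.

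Most markers of other cell types were below the level needed for testing. No epithelial marker reached the level needed for testing. The only tested markers of fibroblasts and of T or NK cells were Pdgfra (1.29 and 1.24 CPM) and Lck (5.41 and 4.55 CPM), and neither passed. Of the B lymphoid markers, Blnk stood at 40.4 and 40.2 CPM, and Ighm fell from 13.9 ± 0.511 to 7.38 ± 0.619 CPM. The neutrophil markers tested, Csf3r (12.6 and 14.5 CPM) and S100a8 (1.37 and 0.877 CPM), did not pass in edgeR. Csf3r passed without control replicate 2 (adjusted p = 0.0141), without Nop16 siRNA replicate 1 (0.0337) and with thinning to equal depth (0.0197), and S100a8 without Nop16 siRNA replicate 1 (0.029). Of 4 dendritic cell markers tested, Itgax rose as above and Clec10a fell by 0.16 on the log2 scale from 395 to 349 CPM. Zbtb46 (5.23 and 4.42 CPM) did not pass. Batf3 (-0.78) passed in edgeR (adjusted p = 0.0246) but not in DESeq2 (0.0927) or with thinning to equal depth (0.073), nor without control replicate 2 (0.196), Nop16 siRNA replicate 1 (0.0935) or Nop16 siRNA replicate 3 (0.0826).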

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

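The alternatives that remove length and GC trends, thin the libraries to equal depth, keep only protein-coding genes, or scale without ribosomal protein genes and pseudogenes were chosen after the data were seen. Tests against a minimum fold moved the counts of genes. At 1.2-fold 2361 genes changed (1108 higher, 1253 lower), and at 1.5-fold 545 changed (270 higher, 275 lower), since such tests leave out the many small changes. Lists past the threshold went from 10 to 4 with an estimated correlation and to 18 with fry, which asks another question. Leaving out each library gave 5839 to 6049 changed genes. The other settings kept the count within 1.5 times, from 5331 in DESeq2 to 6569 with length and GC trends removed. No gene called in both edgeR and an alternative setting changed sign, and the largest shift in the median of all genes from another scaling was -0.023 (log2). Every scaling used only the counts themselves, so none could show a change in the amount of RNA per cell. The share of higher genes ran from 45.9% with scaling by library size only to 51.2%. For the named genes, the planned settings left 1761 values on their side of the threshold, took 33 below it and 5 past it, and the added settings gave 473, 4 and 2. Nop16 stayed past the threshold in every setting that tested it. The labels do not say whether the replicate numbers pair the samples. No shared effect of the number was seen: same-numbered libraries had correlations of 0.017, -0.02 and -0.022, and the others had -0.015 to 0.036. With a block for the replicate number 6429 genes changed (3241 higher, 3188 lower). In simulated counts 48% of 1.2-fold changes were recovered, so small changes can be missed. Far fewer genes were changed there than in the data, so that share need not hold here. The 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real split gave 6482 changed genes (3287 higher, 3195 lower) in edgeR, and 1 of the splits reached each count. The highest of the other 9 splits gave 0, with 141 to 206 genes at an unadjusted p below 0.05 in edgeR. Each of those 9 mixed libraries of both groups, so the difference between the groups widened the spread inside them. Few calls were thus bound to follow there, and a count of 0 is no measure of chance. Other tools were not run on the splits. For gene lists the real split gave 10 and the highest other split 8, so camera with a preset correlation also called lists in mixed groups. With an estimated correlation the numbers were 4 and 0. The mixed splits held the groups in unequal shares, so part of the real difference stayed in them. Their list counts are therefore no measure of false calls by camera either.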

Other observations

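The lists in this part, the classes of site and the test of S-phase genes were chosen after the main results were seen. Beyond the groups described above, genes of the vacuolar ATPase, the proton pump of lysosomes, rose almost as a set: 17 of 18 were higher and 1 lower, with a median log2 fold change of 0.31 (camera adjusted p = 2.07e-05, and adjusted p = 0.0935 with an estimated correlation). Splicing factors of the hnRNP, SR and snRNP families were mostly lower, with 38 of 50 lower and 3 higher (median -0.21), and 14 of 20 nucleoporin genes were lower and none higher. Their camera adjusted p was 3.74e-07 and 8.27e-05, against adjusted p = 0.0935 and 0.105 with an estimated correlation. Of 15 circadian clock genes 8 were lower and 1 higher, and Dbp (-2.15), Per2 (-1.77), Nr1d1 (-1.64) and Per3 (-1.01) fell most (camera adjusted p = 0.00117, and adjusted p = 0.0935 with an estimated correlation). Among Ms4a family genes, Ms4a7, Ms4a14 (1.92) and Ms4a6d (1.26) rose, 3 of 5 tested (camera adjusted p = 0.00359, and adjusted p = 0.0935 with an estimated correlation). Of 7 matrix metalloproteinase and TIMP genes, 4 were higher and 2 lower (camera adjusted p = 0.0982). Mmp12, macrophage elastase, rose from 1443 ± 64 to 4940 ± 266 CPM (1.80), and Mmp13 rose from 21.4 ± 0.562 to 80.8 ± 5.65 CPM (1.94). Of 14 such lists tested, 8 passed camera with a preset correlation and 12 passed fry, while 0 passed camera with an estimated correlation (lowest adjusted p = 0.0892). In a search of annotated 3' UTRs, only the heptamers TGACGTA (z 5.05) and GACGTAA (4.84) lay above the highest permuted z of 4.55, so their carriers lay higher. Both hold the bases GACGTA, so they are not separate hits. Neither occurs in Nop16, but that has no bearing on a control siRNA. The sequence of any control siRNA is not given in the sources used here, so a match to it was not tested.

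Genes that fell after Nop16 siRNA more often carried a short 3' UTR sequence that Nop16 itself holds. In 9728 genes searched, the heptamer CTACCAA had the lowest z (-7.48), below the lowest of 100 permutations (-4.71). All 4 heptamers below that level hold the bases CTACCA, so they are not separate hits. CTACCAG (-5.28) and GCTACCA (-4.72) do not occur in Nop16 transcripts. CTACCAA and ACTACCA (-7.0) do, and overlap as the octamer ACTACCAA in the coding part of exon 5 of the longest transcript (chromosome 13, 54585392 to 54585399, minus strand, GRCm38). Of the heptamers searched, 10.3% occur in Nop16 transcripts. Of 151 genes with this octamer 52.3% were lower, against 23.4% of the 7286 without its inner 6 bases, but the octamer was picked on these same fold changes, so this is no separate evidence. A candidate explanation is seed pairing of the Nop16 siRNA with other transcripts, which stays open because its sequence is not given in the sources used here; 15.9% of the lower genes searched carried the octamer or either heptamer, against 10.1% of the others, and the mitosis median was -0.87 both over all 64 members and over those without the 6 bases.

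Length and GC trends did not account for the fall of mitosis genes, and the calls of these genes did not depend on unequal depth. After thinning all libraries to equal depth, 64 of 64 genes were still lower. Thinning leaves the expected fold changes as they are, so with falls this large it could hardly have ended otherwise. With length and GC trends removed the median was -0.88 (bootstrap interval over genes -0.91 to -0.79). A smaller share of cycling cells may account for it as a hypothesis, since S-phase genes also had a lower median (-0.42). These counts cannot separate that from a direct effect on transcription. Kif11 holds the octamer, which was picked on these same fold changes, and is itself 1 of the 64 genes. An effect by way of that gene was not tested.

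The fall of ribosomal protein genes also held after these corrections, with a median of -0.60 once length and GC trends were removed. The fall was not smaller where pseudogene copies were fewest: the 28 genes with at most 9 copies each had a median of -0.66, and the other 53 had -0.58. Only 1 gene had no matched copy, so counts shared with pseudogenes were not removed by this split. It cannot decide how much they contribute. A lower level of all mRNAs with a 5' terminal oligopyrimidine tract is a candidate explanation: 24 protein-coding genes of that class outside the ribosome had a median of -0.47, below 100% of 10000 random lists matched on expression, length and GC (2.5th percentile -0.07). Not every gene of the class shared the fall: of the full list of 29, 26 were lower, 1 was higher (Eif2s3x, 0.36) and 2 did not pass. Such random lists ignore correlation between members. The full list passed camera (adjusted p = 3.21e-10) but not with an estimated correlation (adjusted p = 0.0892 with an estimated correlation). Whether this follows from the loss of Nop16, from slower growth or from other targets of the siRNA was not tested.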
